A study of Rattus norvegicus with 6 samples.

How the data were processed

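Gene expression was measured in the renal cortex, the outer layer of the kidney, of 6 male Sprague-Dawley rats. Per the labels, 3 rats received the vehicle, corn oil, and 3 received phenolphthalein, a dye once used as a laxative, at 1000 mg/kg/day, each for 4 weeks. The rats were bought at an age of 5 weeks, and each array held the RNA of 1 rat. Total RNA was labelled with a single dye, Cy3, and hybridised to an Agilent rat array. The replicate numbers are those of the labels, and nothing in the labels ties a number in one group to the same number in the other.

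The deposited scanner files hold a spot intensity that Agilent Feature Extraction 10.7.1.1 had background-subtracted and detrended within each array, per the file headers, with no normalization between arrays. The submitters' processing notes name Agilent Feature Extraction 10.7. The deposited value table of the series holds a ratio on a linear scale, with no source for how it was made. Set against the scanner files, each of its 6 columns equalled the processed intensity divided by that array's 75th percentile, with an SD of the log2 difference between 0.000463 and 0.000883. The table is therefore neither centred on genes nor in log units, and its column medians lay between 0.102 and 0.106. Each column matched the scanner file of another replicate of the same group and none matched a file of the other group, so replicate identity within a group is open while the groups are the same in both. The scanner files were used here, with their own replicate names, and the value table served as an alternative. None of its columns was left out (0 columns).

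Each array carried 61657 probes besides control spots. Spots well above background made up 64.8% to 72.1% of the probes per array, no probe was saturated on any array, and 2 to 14 spots per array were flagged as outliers and set to missing. The slope of the spike-in controls lay between 0.967 and 1.01. The number of arrays, 3 per group, limits the precision of each value. The arrays lay on 3 slides scanned on 3 days. All vehicle arrays shared 1 slide, phenolphthalein replicate 1 lay on another, and phenolphthalein replicates 2 and 3 shared the third. Each slide held 1 group only, so no within-slide comparison of the groups exists, and the slide was entered as a random block in an alternative fit. The vehicle slide and the vehicle group cannot be told apart.

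The log2 of the processed intensity minus the log2 of each array's 75th percentile over all non-control probes was the value analysed. A value of 0 is thus the 75th percentile of the array. Probes were named through their RefSeq accession, without versions, with a gene table of the GRCr8 assembly. Of the probes, 27460 matched 1 gene symbol and 34197 matched none. The array design is annotated on the rn4 build, so no coordinates are given. Where several probes measured a gene, the probe with the highest mean over all arrays stood for it. Probes well above background on at least 3 of the arrays were kept, which left 34417 items, 12269 named genes and 22148 unnamed probes. Of 162 genes picked by the naming rule, 88 had over 1 tested probe and 11 had probes that differed in sign.

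The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, both directions), with Benjamini-Hochberg adjustment over all items and a threshold of 0.05. Standard errors are those of limma, and SDs are between the 3 animals of a group. In total 39 gene lists for kidney segments, other cell types and responses, each with at least 5 tested members, were tested with camera at a preset correlation of 0.01 and adjusted over the lists. The lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 largest changes in each direction among genes past the threshold whose groups do not overlap or, if none passed, the 5 genes with the smallest p in each direction, and up to 4 members with the smallest p of each list described. LOC, RGD and similar provisional names were left out of its first part. A probe not well above background on any array of a group has only a bound there. Its change is given as at least N-fold, the brighter group's mean against a dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own.

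Data were simulated 20 times with the real means and SDs of 34399 items for phenolphthalein against vehicle, with 200 items changed. The fit recovered 26.1% of the items changed 1.5-fold, 53.9% of those changed 2-fold, 86.5% at 4-fold and 91.7% at 8-fold. False calls averaged 6.45 per simulation. The adjusted p depends on how many items change. These shares therefore do not carry over to data in which fewer items change. Lists shifted by 0.5 log2 were recovered in 100% of cases, and 0.135% of the unchanged lists were called. That simulation drew genes independently, so it does not test camera on correlated genes.

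The alternatives were normexp background correction (offset 50), quantile normalization, median centring, no filter or a filter on all 6 arrays, the value table, the slide as a random block, the replicate number as a block, leaving out each array, no intensity trend, array weights, other probe rules, outlier spots kept, other thresholds, and camera with an estimated correlation. Normexp used the median spot and local background intensity, since the scanner files used here carry no mean signal. A liver marker score as a covariate, and the alternatives for the correlation between arrays, were added after seeing the data. The score is the median over 36 tested liver genes of each gene's deviation from its mean over the arrays.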

Results

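The data cover the renal cortex of 3 rats given corn oil and 3 rats given phenolphthalein at 1000 mg/kg/day for 4 weeks, 1 array per rat. The comparison asks which genes differ in the renal cortex after phenolphthalein. The arrays resembled each other closely. Over the tested items, Pearson's r between arrays of different groups averaged 0.990, and it lay between 0.987 and 0.992 over all pairs. The lowest value joined vehicle replicate 2 and phenolphthalein replicate 1. The first principal component held 26.8% of the variance and set phenolphthalein replicate 1 (score -57.8) apart from the other phenolphthalein arrays (-5.43 and -0.0307), while the vehicle arrays scored 12.6, 35.6 and 15.2. These correlations run across genes, which are not independent replicates.

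No single gene passed the threshold in either direction: 0 genes were higher and 0 lower with phenolphthalein (limma, smallest adjusted p = 0.307). The gene closest to the threshold was Atp7a, which encodes a copper-transporting ATPase. Its level was -1.64 ± 0.09 in vehicle and 0.54 ± 0.39 in phenolphthalein (log2 relative to the 75th percentile, SD, n = 3 each), a difference of 2.19 (SE 0.19, limma adjusted p = 0.307), and both of its probes were higher. The other genes with the smallest p on the higher side were Asrgl1, an asparaginase-like enzyme (log2 fold change 1.08), Pom121l2 (0.80), Cyb5r1 (0.54) and Tatdn3 (0.79). On the lower side they were Plcxd2 (-0.75), Gprasp3 (-0.69), Slc12a3 (-0.39), Armcx6 (-0.95) and Fgr, a Src-family kinase of myeloid cells (-0.85). Each of these 10 genes had non-overlapping groups and an adjusted p between 0.307 and 0.389. They were picked by their p in the same arrays, so the lack of overlap is no separate support. Slc12a3, the thiazide-sensitive sodium chloride cotransporter of the distal convoluted tubule, had 3 tested probes, of which 2 were higher, and the median over its probes gave 0.02. Cyb5r1 had 4 tested probes, of which the one used was the highest and the lowest was at 0.0000875; the median over its probes gave 0.03.

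At an unadjusted p under 0.05, 1346 items were higher and 1708 lower, against 1721 expected by chance for both directions together. These 3054 items compare with 1102 to 1558 in the other splits of the same 6 arrays into sides of 3. The real split also parts the vehicle slide from the others. With the slide as a random block, 1023 items were higher and 1305 lower (limma, smallest adjusted p = 0.603). Of all items, 15.7% had groups that did not overlap, where chance gives 10%. Leaving out 1 array changed the count of genes in either direction by at most 1. Without phenolphthalein replicate 2, Atp7a was called higher and Ubd, a ubiquitin-like gene of the interferon response, lower; without phenolphthalein replicate 3, Prl3d4 was called higher, and without vehicle replicate 1, 1 unnamed probe was called lower. Ubd stood at 2.72 in the array left out, within its vehicle values of 2.18 to 2.95, and at -4.20 and -3.18 in the other phenolphthalein arrays. Prl3d4 stood at -5.13 in the array left out, within its vehicle values of -5.27 to -4.90. Both calls thus rest on leaving out the phenolphthalein array that did not differ. Ubd and Prl3d4 are named after their values were seen.

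Interferon response genes, MHC class II genes, macrophage and monocyte markers and T and NK cell markers were lower as lists with phenolphthalein by camera with the preset correlation. None of these 4 calls held with an estimated correlation (adjusted p = 0.816 for each with an estimated correlation). In the interferon response list, 34 of 38 tested members had lower values, with a median log2 fold change of -0.54, and 18 of them were lower at an unadjusted p under 0.05. The members with the smallest p were Ifi44 (-0.77, SE 0.11), Rtp4 (-1.11, SE 0.27), Tap1, the peptide transporter of antigen presentation (-0.72, SE 0.18), and Irf7, a transcription factor of the interferon response (-1.01, SE 0.27). Ifi44 alone passed when adjusted over the list alone, and 0 members passed over all items. The camera adjusted p of the list with the preset correlation was 5.51e-11. Without vehicle replicate 2, the median was -0.35 and the list was still called (camera adjusted p = 2.02e-05).

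All 9 tested genes of MHC class II presentation had lower values, with a median of -0.41, and 4 passed when adjusted over the list alone. These 4 were Cd74, the invariant chain of MHC class II (5.39 ± 0.16 in vehicle and 4.92 ± 0.11 in phenolphthalein, SD, n = 3 each), RT1-Db1 (log2 fold change -0.81), RT1-Da (-0.41) and RT1-Bb (-0.55). RT1-Db1 had 5 tested probes, 1 of which was higher. Of 22 macrophage and monocyte markers, 19 had lower values, with a median of -0.44. When adjusted over the list alone, 13 passed, of which 1, Mrc1, was higher. Among the 4 with the smallest p, the lysosomal protein Cd68 (-0.57), Aif1 (-0.50) and the adaptor Tyrobp (-0.49) were lower, while the mannose receptor Mrc1 was higher (1.1, SE 0.23; 0.54 by its other probe). All 21 tested T and NK cell markers had lower values, with a median of -0.40, among them Cd8a (-0.69), the cytotoxic granule genes Nkg7 (-0.47) and Prf1 (-0.51), and Cd3d (-0.40); 0 passed when adjusted over the list alone. Camera with the preset correlation called MHC class II presentation (adjusted p = 2.49e-06), macrophage markers (8.02e-09) and T and NK cell markers (2.67e-08). With an estimated correlation, each of these calls was lost (camera adjusted p = 0.816). With normexp, the median of the T and NK cell markers was -0.25. Without phenolphthalein replicate 1, Nkg7 was at -0.29 and Prf1 at -0.30, and without vehicle replicate 2, Cd3d was at -0.26. B and plasma cell markers (median -0.43) and neutrophil markers (median -0.06) were not called, with camera adjusted p of 0.327 and 0.474. Leaving out 1 array gave B and plasma cell medians of -0.55 to -0.19.

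**Figure D1:**
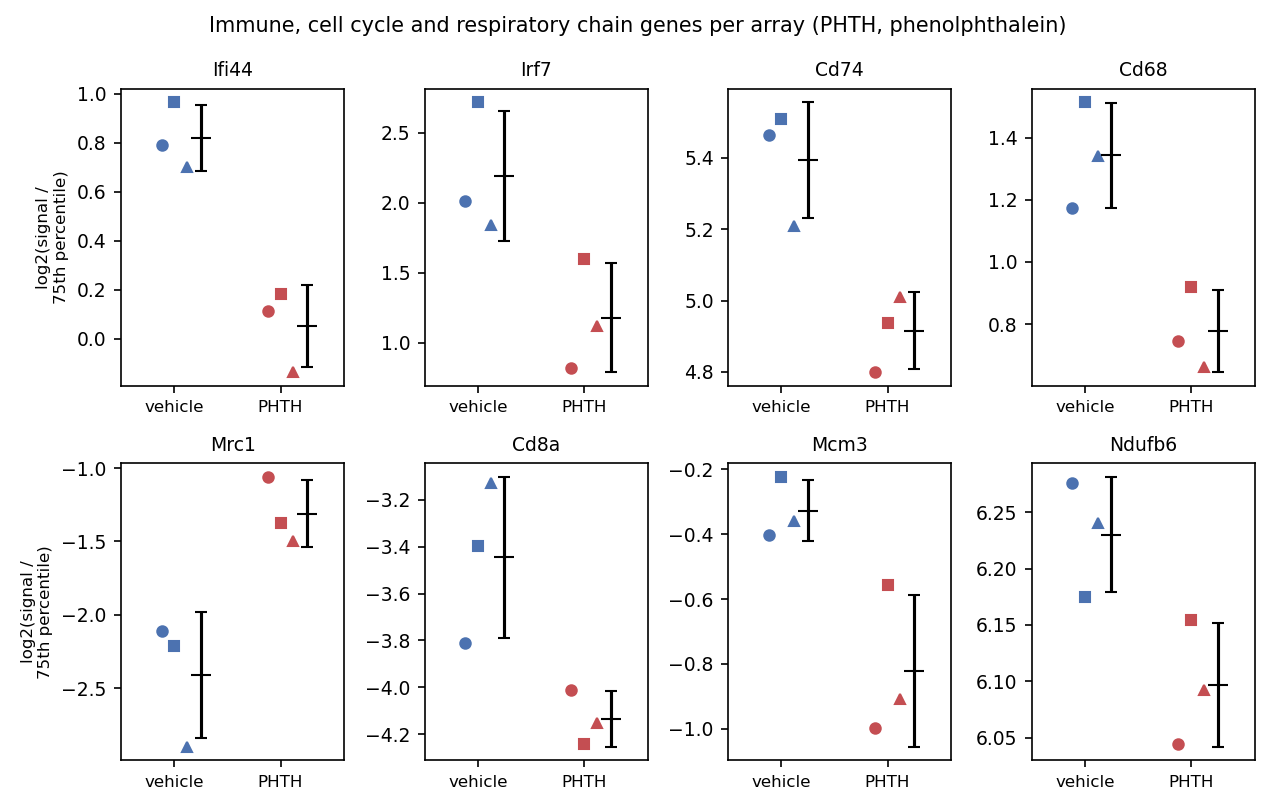
Log2 signal relative to the 75th percentile of each array (y axis) for 8 named genes in vehicle (blue) and phenolphthalein (red, PHTH) arrays. Circles, squares and triangles are replicates 1, 2 and 3, and bars show the mean and SD of 3 arrays. The groups do not overlap for any of the 8 genes, and Mrc1 alone is higher with phenolphthalein (1.1).

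All vehicle arrays lay on 1 slide, so the slide and the group cannot be told apart for these lists. With the slide as a random block, the same 6 lists were lower and the same list was higher. Other ways of splitting the same 6 arrays into sides of 3 gave between 1 and 15 called lists, against 7 for the real groups. Within the phenolphthalein group, the array on its own slide was lower than the pair on the other slide by a median of -0.23 over the 90 members of these 4 lists, where the groups differed by -0.45.

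Cell cycle genes were lower as a list with the preset correlation (camera adjusted p = 0.000190) and were not called with an estimated one (adjusted p = 0.817 with an estimated correlation). Of 44 tested members, 37 had lower values, with a median of -0.23. The members with the smallest p were the replication licensing factor Mcm3 (-0.49), the spindle protein Nusap1 (-0.56), E2f1 (-0.40) and Gins1 (-0.38), and 0 passed when adjusted over the list alone. E2f1 had 4 tested probes, 1 of which was higher. The median was -0.10 without vehicle replicate 3. Oxidative phosphorylation genes were lower by a small amount with the preset correlation (camera adjusted p = 0.00340) and were not called with an estimated one (adjusted p = 0.817 with an estimated correlation). Of 49 tested members, 41 had lower values, with a median of -0.05, among them the complex I subunits Ndufb6 (-0.13) and Ndufs8 (-0.13) and the complex III subunit Uqcrb (-0.09), while the complex II subunit Sdha was at 0.09 (-0.02 by its other probe). The call was also lost with quantile normalization, where the median shrank to -0.02 (adjusted p = 0.362), and without phenolphthalein replicate 1, where it was -0.03 (adjusted p = 0.114). Without the intensity trend the median stayed at -0.05 and only the call was lost (adjusted p = 0.0634).

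Targets of the xenobiotic receptors CAR and PXR were the only list called higher by camera with the preset correlation (adjusted p = 1.37e-05), and the call was lost with an estimated one (adjusted p = 0.816 with an estimated correlation). Of 23 tested members, 18 had higher values, with a median of 0.28. The array means over the members, relative to each gene's vehicle mean, overlapped between the groups. In the order of the replicates they were 0.54, 0.01 and -0.55 in vehicle and 0.66, 1.36 and 0.37 in phenolphthalein. Vehicle replicate 1 thus lay above phenolphthalein replicate 3. Cyp2b2, a cytochrome P450 of drug metabolism, was at -2.58 ± 0.05 in vehicle and -0.77 ± 1.07 in phenolphthalein (SD, n = 3 each), a log2 difference of 1.81 (SE 0.48), and all 5 of its tested probes were higher. Cyp2b1 and the glucuronosyltransferase Ugt2b1 were not well above background on any vehicle array and were at least 2.84-fold and at least 2.41-fold higher with phenolphthalein. Without phenolphthalein replicate 2, the array with the highest liver marker score, these bounds were 1.66-fold and 1.45-fold, and without phenolphthalein replicate 3 they were 4.48-fold and 3.87-fold. Cyp2b1 and Cyp2b2 are near-identical paralogs, so signal shared between their probes is not excluded. The efflux transporter Abcb1b differed by 0.97 (SE 0.35). In the list, 7 members were higher and 0 lower at an unadjusted p under 0.05, and 0 passed when adjusted over the list alone (smallest adjusted p = 0.0531). Without vehicle replicate 1, the median was 0.44. Kept to probes well above background on all 6 arrays, the list median was 0.21 (camera adjusted p = 0.00696, preset correlation). The probes that filter leaves out include those of Cyp2b1, Ugt2b1 and Cyp2c6v1. Cyp2c6v1 (log2 fold change 2.60) was well above background on 2 of 3 vehicle arrays. Part of the list's large rises thus rests on dim vehicle signals.

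Liver genes varied between arrays alongside this list. Albumin (Alb) stood at 1.82, 0.91 and -0.08 in the vehicle arrays and at 0.67, 3.16 and 1.04 in the phenolphthalein arrays, in the order of the replicates. Of 36 tested liver markers, 21 were highest in phenolphthalein replicate 2, where 6 would be expected by chance, and 8 lay above the 75th percentile on every array and are counted here as expressed by the kidney as well. Of the 36, 1 is also a member of a fixed list. The liver marker score was -0.10 in vehicle and 0.07 in phenolphthalein, a difference of 0.17 (SE 0.49, two-sided exact permutation p = 0.7, where 0.1 is the smallest p this design allows). Without the 8 markers above the 75th percentile on every array, the score differed by 0.36 (SE 0.72, two-sided exact permutation p = 0.8) and stood at 1.55 in phenolphthalein replicate 2. With all 36 markers, phenolphthalein replicate 2 had both the highest score (0.91) and the highest Cyp2b2 (0.34). Vehicle replicate 1 had a higher score (0.39) than phenolphthalein replicates 1 (-0.48) and 3 (-0.22) and a lower Cyp2b2 than both.

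**Figure D2:**
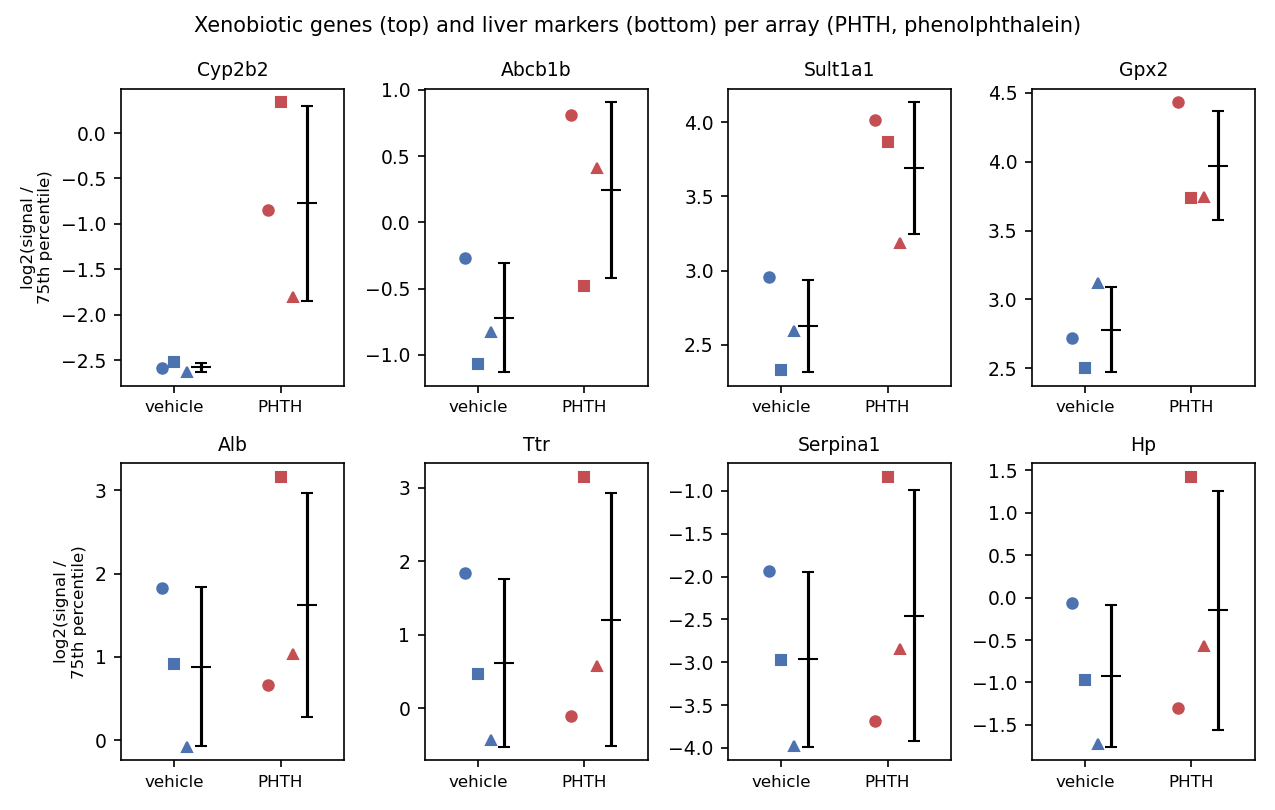
Log2 signal relative to the 75th percentile of each array (y axis) for 4 genes of foreign-compound metabolism (top) and 4 liver markers (bottom) in vehicle (blue) and phenolphthalein (red, PHTH) arrays. Circles, squares and triangles are replicates 1, 2 and 3, and bars show the mean and SD of 3 arrays. The liver markers are highest in phenolphthalein replicate 2 (Alb 3.16), and Cyp2b2 is higher in every phenolphthalein array than in every vehicle array.

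Several lists that bear on kidney injury or toxicity were not called. Tubular injury and repair markers had a median of -0.03 over 31 members, with 1 higher and 2 lower at an unadjusted p under 0.05 and Cst3 at -0.39. Nrf2 targets had a median of -0.03 over 37 members, of which Gpx2, a glutathione peroxidase, alone passed when adjusted over the list alone (log2 fold change 1.19, adjusted p = 0.0452 over that list). Targets of p53 had a median of 0.01 over 28 members, and 3 passed when adjusted over the list alone, the growth-arrest gene Gadd45a (0.28) on the higher side and Dcxr (-0.24) and Ddit4 (-1.05) on the lower. Targets of AhR had a median of -0.00098 over 7 of 11 listed members: Ahrr, Aldh3a1, Exoc3, Nfe2l2, Nqo1, Scin and Ugt1a6. None of these is a cytochrome P450 such as Cyp1a1, so the list says little about AhR activity. Proximal tubule transporters had a median of -0.03 over 37 members, with the glucose transporter Slc2a2 at 0.21 and the phosphate transporter Slc34a1 at -0.12. The camera adjusted p values of these lists were 0.762, 0.861, 0.656, 0.733 and 0.732 in that order.

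**Figure D3:**
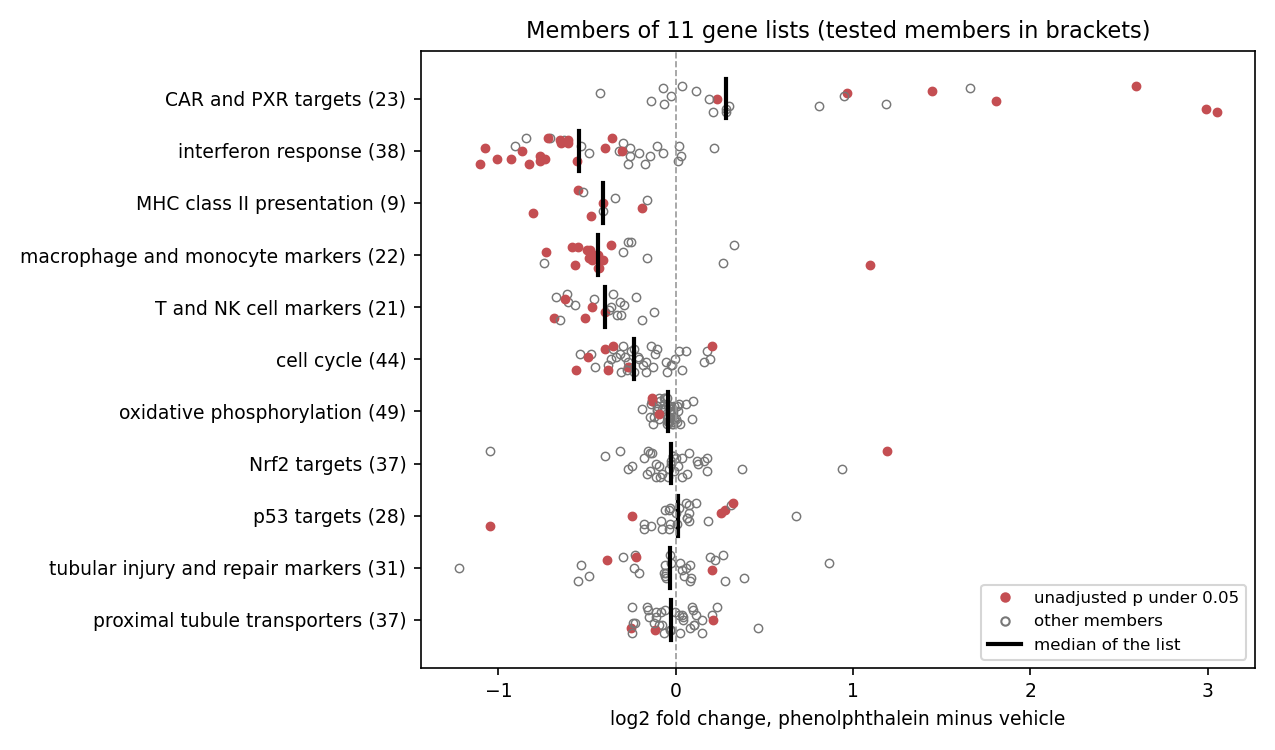
Log2 fold change, phenolphthalein minus vehicle (x axis), of the tested members of 11 gene lists (y axis), with 1 point per gene, filled where the unadjusted p is under 0.05, and a bar at the list median. The 4 immune lists have medians between -0.54 and -0.40, CAR and PXR targets have a median of 0.28, and the injury, Nrf2, p53 and proximal tubule lists have medians between -0.03 and 0.01. The points of Cyp2b1 and Ugt2b1 rest on vehicle signals not well above background. Cyp2c6v1 was well above background on 2 of 3 vehicle arrays.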

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

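The liver marker score and the alternatives for the correlation between arrays were chosen after seeing the data. The count of genes was 0 higher and 0 lower under each processing, threshold and model alternative that kept all 6 arrays, with the replicate block (0 and 0) among them. Same-numbered animals did not deviate together (correlations of -0.00606, -0.0150 and 0.025), and not every array correlated best with its own number. These values give no sign that the number pairs the samples, though 3 arrays per group cannot exclude it. With the block, 1 list was higher and 6 lower, as without it. Leaving out 1 array gave 0 to 1 genes higher, 0 to 1 lower, 1 to 2 lists higher and 5 to 8 lists lower. With an estimated correlation, 0 lists were higher and 0 lower. The estimated correlations between members of the called lists were 0.166 to 0.482. The p also rose in lists with an estimate below the preset 0.01. For neutrophil markers (estimate -0.108), the unadjusted camera p went from 0.219 to 0.270. The loss of calls can therefore not be put down to these correlations alone, and its cause was not tested. The mean correlation between arrays of different groups, 0.990, was 0.994 with normexp, 0.988 without a filter and 0.992 with the filter on all 6 arrays. Of 780 list medians under alternatives, 709 kept direction and side of the threshold, 10 lost a call, 7 gained one and 54 changed sign. Some alternatives left the medians of the called lists unchanged, so there only the call could move. They were the replicate block, no intensity trend, outlier spots kept and the estimated correlation. The count of kept directions is thus partly given by the settings. The 7 gained calls were in lists not called otherwise. They were the unfolded protein response with normexp (adjusted p = 0.0307) and without vehicle replicate 3 (adjusted p = 0.00233), and heat shock proteins without vehicle replicate 3 (adjusted p = 0.0143) and without phenolphthalein replicate 3 (adjusted p = 0.00551). The others were erythroid genes without vehicle replicate 1 (adjusted p = 0.0101), PPARalpha targets without vehicle replicate 2 (adjusted p = 0.0267) and intercalated cells without phenolphthalein replicate 1 (adjusted p = 0.0367). None of the 7 called lists changed sign. Of 1934 values of 102 named genes, 1932 kept both, 1 gained a call and 1 changed sign. The sign change was Slc12a3, at 0.016 with the median of its probes. These genes were picked by their p in the same arrays and none had passed, so this count is no independent check.

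The sign changes were of medians near 0 in lists that were not called, and the cause was not tested. With normexp they were 0.0035 for tubular injury, 0.025 for AhR targets, -0.015 for PPARalpha, 0.011 for renin-angiotensin and -0.0078 for vitamin D; with quantile normalization 0.0042 for AhR and 0.0038 for renin-angiotensin; with median centring 0.0062 for AhR. With array weights they were 0.032 for AhR, -0.0095 for PPARalpha, 0.00061 for renin-angiotensin and -0.013 for vitamin D; with the median of a gene's probes -0.0094 for PPARalpha, -0.023 for principal cells and -0.018 for intercalated cells. Leaving out 1 array gave ranges of -0.097 to 0.017 (proximal tubule), -0.047 to 0.017 (tubular injury), -0.088 to 0.0045 (Nrf2), -0.049 to 0.039 (AhR), -0.049 to 0.069 (PPARalpha), -0.015 to 0.064 (cholesterol), -0.055 to 0.014 (renin-angiotensin), -0.0016 to 0.063 (gluconeogenesis), -0.047 to 0.11 (vitamin D), -0.14 to 0.050 (oestrogen), -0.0097 to 0.054 (hypoxia), -0.023 to 0.047 (complement), -0.065 to 0.041 (podocyte), -0.013 to 0.12 (thick ascending limb), -0.14 to 0.19 (distal convoluted tubule), -0.067 to 0.11 (principal cells), -0.041 to 0.13 (intercalated cells), -0.14 to 0.023 (inner medulla), -0.16 to 0.029 (neutrophils) and -0.14 to 0.049 (fat and adrenal). Without a change of sign, medians that moved by over 1.5 times ranged from -0.13 to -0.00061 (glucuronidation), 0.0021 to 0.030 (p53), -0.13 to -0.04 (heat shock), 0.012 to 0.11 (fatty acid synthesis), 0.022 to 0.12 (clock), -0.13 to -0.0014 (immediate early), 0.013 to 0.040 (endothelium), -0.55 to -0.19 (B and plasma cells), 0.013 to 0.13 (fibroblast and matrix), -0.21 to -0.03 (erythroid) and -0.46 to -0.03 (urothelium). Signal over background limits Cyp2b1, Ugt2b1 and Lum, which have only bounds in vehicle.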

Other observations

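The other lists were also fixed beforehand, and none was called by camera with all 6 arrays and the processing of the report; 5 of them were called under an alternative. Glucuronidation and sulfation genes had a median of -0.07 and a mean of 0.19, so that median and test differed in sign; 2 of its 18 members passed when adjusted over the list alone, the sulfotransferase Sult1a1 (log2 fold change 1.06, SE 0.24) and Ugt2b1, while the highly expressed Ugt2b35 was at -0.82. The renin-angiotensin and mineralocorticoid list had a median of -0.02, with the glucocorticoid-responsive Fkbp5 at 1.32 (SE 0.41; 0.79 without vehicle replicate 2) and the prostaglandin synthase Ptgs2 at -1.20 (SE 0.27), the latter well above background on 1 of 3 phenolphthalein arrays. Complement and coagulation genes had a median of 0.04, of which prothrombin, F2, alone passed when adjusted over the list alone (1.48, SE 0.27). Fibroblast and matrix genes had a median of 0.04; Col1a1 (-0.37), Tgfb1 (-0.64), Mmp2 (-0.39) and Lum, at least 1.09-fold higher, passed when adjusted over the list alone. Without vehicle replicate 1 or phenolphthalein replicate 1, the Lum bound fell below 1 (0.961 and 0.991). The p values of Lum and Ugt2b1 take vehicle signals not well above background as measured, so that they passed is uncertain.

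Among metabolic lists, medians were 0.01 for PPARalpha targets (Acot12 at 0.59, Ucp2 at -0.31), 0.03 for gluconeogenesis and ammoniagenesis (Pck1 at 0.27), 0.04 for cholesterol synthesis, 0.03 for fatty acid synthesis (Elovl6 at 0.52) and 0.01 for vitamin D, calcium and phosphate genes. Stress and signalling lists had medians of -0.09 (unfolded protein and amino acid response), -0.10 (heat shock proteins), 0.03 (hypoxia response), -0.05 (oestrogen- and sex-dependent genes), 0.05 (clock genes) and -0.10 (immediate early genes). Cell type medians were -0.03 for podocytes, 0.05 for thick ascending limb, 0.01 for distal convoluted tubule, 0.06 for principal cells, 0.02 for intercalated cells, -0.05 for inner medulla and thin limb, 0.02 for endothelium, -0.13 for erythroid genes, -0.06 for fat and adrenal genes and -0.12 for urothelium. Leaving out 1 array moved the erythroid median between -0.21 and -0.03 and the urothelium median between -0.46 and -0.03. Members past the threshold when adjusted over the list alone were Slc12a3 and Sgms2 (0.47) of the distal convoluted tubule, Slc6a12 (-0.46) and Cald1 (-0.42) of the inner medulla, and Pnpla2 (0.40) and Cyp17a1 (-0.68) of fat and adrenal. Median, mean and test differed in sign in 5 lists: glucuronidation, renin-angiotensin, hypoxia, podocyte and distal convoluted tubule.

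Of the tests below, only the count of lists over other splits was set out before its result was seen; the others were chosen, or had their bounds changed, after values bearing on them were known. The first pattern is the higher CAR and PXR list. A candidate explanation is RNA from liver in unequal amounts, since Alb, Ttr, Serpina1 and Hp share 1 profile over the arrays. With the liver marker score in the model, the mean of the list's members still differed by 0.667 (SE 0.255, 95% interval -0.145 to 1.48). Without the score it differed by 0.799 (SE 0.431), so the arrays do not decide for the list as a whole. Both means take the log2 differences of Cyp2b1 (2.99) and Ugt2b1 (3.05) as measured, although these genes have only bounds in vehicle. For Cyp2b2 alone, the difference from the score was 1.63 higher in phenolphthalein (SE 0.453), which argues against unequal liver RNA as its whole source, although with a fitted slope on the score the difference of 1.66 had an interval that reached -0.0172. Liver RNA in which Cyp2b2 is itself raised stays open, as does expression in the kidney: subtracting the score left 0.731 of the within-group SD of Cyp2b2.

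The second pattern is the set of lower immune lists. A single vehicle animal with high immune transcripts stays open, since vehicle replicate 2 was the highest array in each of the 4 lists. Without it, the array means over the members still differed by -0.31 (SE 0.112), with a 95% interval of -0.66 to 0.05, against -0.43 (SE 0.153) with all arrays. By list with all arrays, the 95% interval was -1.09 to 0.10 for interferon response and -0.65 to 0.02 for macrophage markers. It was -0.79 to -0.08 for T and NK cell markers and -0.81 to -0.06 for MHC class II. No list passed a t test of its array means adjusted over the 4 lists (adjusted p of 0.066 to 0.081). Without vehicle replicate 2, the interval excluded 0 for T and NK cell markers alone (-0.33, interval -0.63 to -0.03, not adjusted for the 4 lists). Its two-sided exact permutation p was 0.1, the smallest that 5 arrays allow. The other vehicle arrays lay above every phenolphthalein array in each list. The slide stays open: the slides within the phenolphthalein group differed by 0.502 times the group difference, and the vehicle slide holds no other group. Fewer macrophages may contribute; 1 macrophage marker, Mrc1, was higher at an unadjusted p under 0.05 where 0.55 would by chance, which decides nothing. An effect of phenolphthalein on immune cells was not tested beyond the group comparison.

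The third pattern is the number of calls itself. The 6 arrays can be split in 10 ways, too few for a share under 0.05. For genes the count decides nothing: the real split gave 0, other splits up to 7, and with a real count of 0 all 10 of the 10 splits give as many by construction. For lists, the real split gave 7 and the others up to 15, and 7 of the 10 splits gave as many. At an unadjusted p under 0.05, the real split had 3054 items, more than any other split (1102 to 1558); this count was looked at after its values were known, and the real split also parts the slides. The split with 15 lists set vehicle replicate 1 and phenolphthalein replicates 1 and 3 against the rest. The members of the 7 called lists had estimated correlations of 0.166 to 0.482, where the test was preset at 0.01.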
